A study of Mus musculus with 24 samples.

How the data were processed

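RNA of mouse liver was sequenced in 24 libraries, 4 for each of 6 genotypes, and grouped by the genotype given in the labels. The labels give neither sex nor a batch, litter or day, and do not say that each library came from a separate animal. Per the labels' protocols, livers of C57BL/6J mice aged 2 months were snap frozen, total RNA was extracted with Trizol, and stranded libraries of polyadenylated RNA were sequenced as single reads of 75 bp.

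The deposited values are raw counts per Ensembl gene, not normalised, with 1 column per library. Per the submitters' processing notes, the authors used Trimmomatic 0.36, HISAT2 2.1.0, HTSeq and the genome build GRCm38 to make these counts. The version of HTSeq, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping genes on opposite strands may share counts. The values were checked to be whole numbers with different totals, from 10494080 to 13057467 per library. They cover 33019 gene identifiers, of which 32938 had a symbol and coordinates in GENCODE release M21 on GRCm38 and 81 did not.

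All calculations from the counts onward were made with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were filtered with filterByExpr on the 6 groups, which left 15851, and libraries were scaled by TMM. A model with 1 mean per genotype (18 residual degrees of freedom) was fitted to the 24 libraries with edgeR's robust quasi-likelihood method. Each of 9 pairs of genotypes and the interaction of the single losses was tested in it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM on TMM-scaled totals, and principal components were computed from log2 CPM with a prior count of 2. These choices, the gene lists, the rule for naming genes and the alternatives were set before the data were examined, except where a later choice is stated.

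A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is given as a bound. Where a group had 1 to 3 counts, the ratio is given with its 95% exact counting interval. List medians were also taken with such genes at their bounds, in 270 combinations of list and comparison, of which 39 held such a gene and 0 moved.

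Genes were named by a rule. It took the 4 targeted genes, and in each comparison the 6 largest increases and 6 largest decreases among called genes. These had a mean of at least 5 CPM in the higher group and, outside the interaction, all 4 libraries of one group above all 4 of the other. Symbols of predicted genes (Gm or Rik) were passed over. From each gene list described, up to 4 members with the smallest adjusted p and up to 2 with the highest mean CPM could be named. Genes named outside the rule are stated as chosen after their values were seen. Some genes that met the rule are not reported here. Lists of cell types, pathways and sex-dependent genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists with at least 4 tested members. The result of each list is given for DKO versus WT, and for the other comparisons those that describe them.

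Changes opposed by p62 or Nrf2 loss were counted as genes called in DKO versus WT and called in the other direction in the triple knockout versus DKO. Both comparisons use the DKO libraries, so the count is given beside that of independent lists. Slopes come from 6 splits of the DKO libraries in which no library served both sides. A planned set of 20 simulations left all groups unchanged. Another 20, chosen after the results were seen, kept the DKO change and left the triple knockouts unchanged from DKO.

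The test was run on counts simulated for DKO versus WT from the means, dispersions and library sizes of these libraries (15161 genes after filtering). Of 50 genes per fold change, 22% were called in the right direction at 1.5-fold, 56% at 2-fold, 82% at 4-fold and 96% at 8-fold. Of 14946 unchanged genes 6 were called. The real data had far more calls, so these shares need not hold there.

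Alternatives were DESeq2 in place of edgeR, DESeq2 size factors in edgeR, total counts alone, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. For list tests they were an estimated correlation, fry and the block. No library was left out of the reported values.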

Results

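Liver RNA was measured in 24 libraries, 4 for each of 6 genotypes of C57BL/6J mice at 2 months of age. Wild-type livers (WT) stood beside livers labelled with a hepatic deletion of Atg5, which is needed to form autophagosomes, and livers labelled with a hepatic deletion of Tsc1, which restrains the growth kinase complex mTORC1. A further group is labelled with both deletions (DKO). The remaining 2 groups are labelled as triple knockouts (TKO), with a further deletion of either p62, the autophagy receptor encoded by Sqstm1, or Nrf2, the transcription factor of antioxidant and detoxification genes encoded by Nfe2l2. The total count per library ran from 10494080 to 13057467. It was 11283916 to 11675002 in WT, 11707734 to 13057467 in Atg5 KO, 11403975 to 12465339 in TSC1 KO, 11403175 to 13007760 in DKO, 11104112 to 12795277 in p62 TKO and 10494080 to 12221723 in Nrf2 TKO. Levels are in CPM with library sizes scaled by TMM, given as mean ± SD with n = 4 libraries per group, and changes of genes are log2 fold changes ± SE. Medians of gene lists are medians of log2 fold changes over the members tested. The list test (camera) used a preset correlation between genes, and a second adjusted p, with an estimated correlation, is given for the lists that passed with it as well. The other lists called did not pass with it. Unless a list test is named, adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15851 genes tested. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples.

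The targeted genes were examined first. Atg5 (ENSMUSG00000038160, chromosome 10, 44268358 to 44364291 on GRCm38, plus strand) stood at 26.8 ± 3.75 CPM in WT, 43 ± 4.27 in Atg5 KO, 83.7 ± 3.75 in TSC1 KO, 23.4 ± 2.28 in DKO, 38.1 ± 3.26 in p62 TKO and 41 ± 8.22 in Nrf2 TKO. Its count was thus higher in the libraries labelled Atg5 KO than in WT (0.68 ± 0.12, adjusted p = 0.00027, or 1.06 with total counts alone) and higher still in those labelled TSC1 KO (1.64 ± 0.13, adjusted p = 1.5e-08). Tsc1 (ENSMUSG00000026812, chromosome 2, 28641228 to 28691167, plus strand) stood at 35.1 ± 1.53 CPM in WT, 32.6 ± 8.74 in Atg5 KO, 31 ± 1.99 in TSC1 KO, 36.6 ± 12.1 in DKO, 22.4 ± 2.43 in p62 TKO and 30.1 ± 6.55 in Nrf2 TKO, and did not pass the test in TSC1 KO (-0.18 ± 0.19, adjusted p = 0.56), although it was lower in p62 TKO than in DKO (-0.71 ± 0.19, adjusted p = 0.0042, or -1.17 with total counts alone) and than in WT (-0.65 ± 0.19, adjusted p = 0.0073, but -0.13 and not passing with total counts alone). Counts over a whole gene include exons outside a deleted part, and the sources used here do not name the exons deleted, so these counts neither show nor exclude the deletions, and Atg5 KO, TSC1 KO, DKO and TKO name the libraries as labelled throughout. Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827, minus strand) stood at 578 ± 78.5 CPM in WT, 824 ± 142 in Atg5 KO, 738 ± 72 in TSC1 KO, 961 ± 157 in DKO, 456 ± 226 in p62 TKO and 659.5 ± 211 in Nrf2 TKO. It was lower in p62 TKO than in DKO (-1.07 ± 0.25, adjusted p = 0.0015), with 249, 439, 363 and 774 CPM in the 4 p62 TKO libraries, and did not pass against WT (-0.34 ± 0.25, adjusted p = 0.27). Without p62 TKO replicate 4, the highest of them, it passed against WT (-0.72, adjusted p = 0.011), and with total counts alone its change against WT was 0.18 and did not pass. It overlaps Mrnip on the other strand, and the strand setting of the counting is not given in the sources used here. Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, minus strand) stood at 66.9 ± 10.2 CPM in WT, 113 ± 17.8 in Atg5 KO, 93.2 ± 10.9 in TSC1 KO, 113 ± 32.7 in DKO, 123 ± 4.95 in p62 TKO and 11.7 ± 4.24 in Nrf2 TKO, where it was lower than in DKO in 4 of 4 libraries (-3.26 ± 0.21, adjusted p = 8.3e-11).

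**Figure D1:**
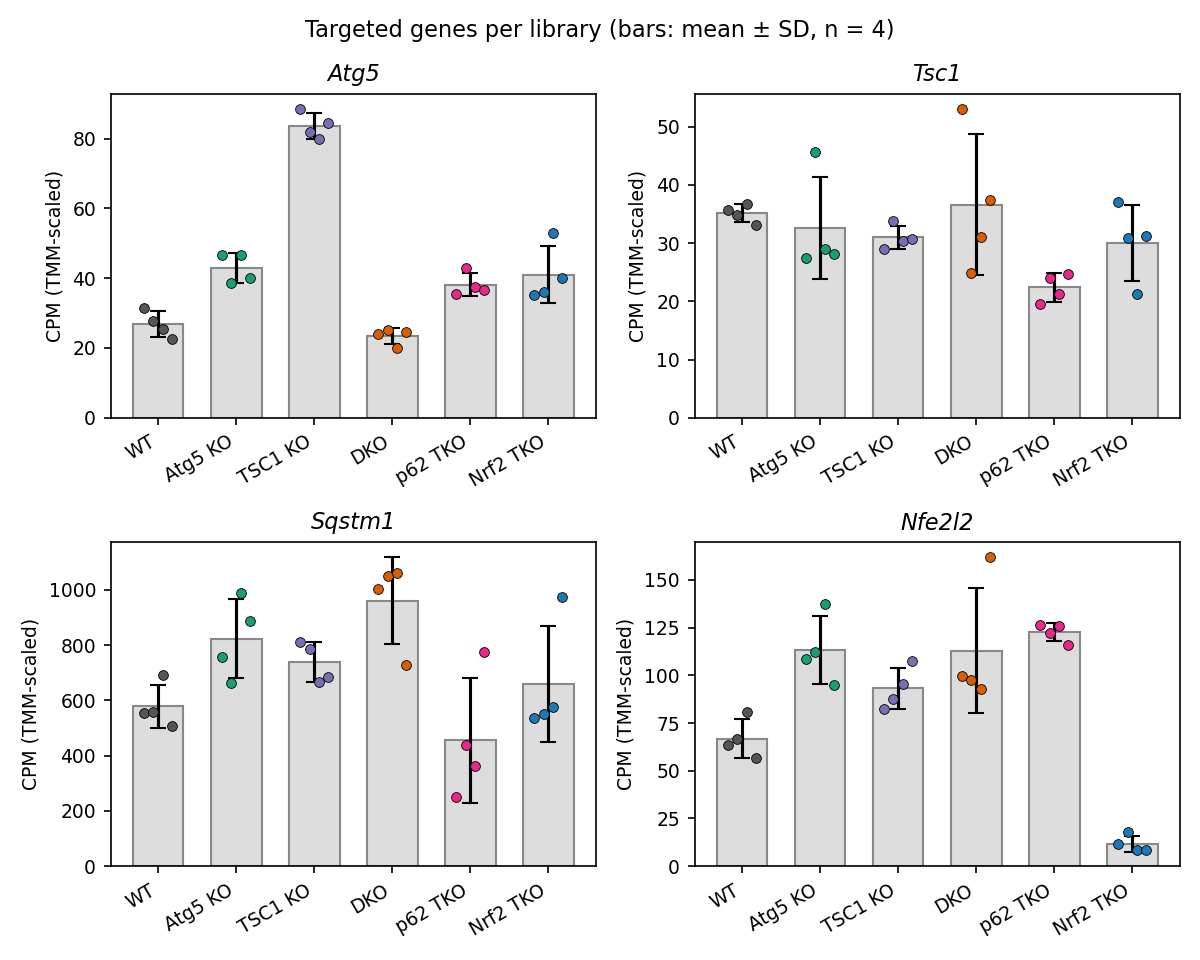
CPM (TMM-scaled, linear axis from 0) of the 4 targeted genes in each of the 24 libraries, with points for libraries and bars for the mean ± SD of n = 4. Nfe2l2 lies at 11.7 CPM on average in Nrf2 TKO against 113 in DKO, whereas Atg5 lies higher in Atg5 KO (43) than in WT (26.8).

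Across the 2000 most variable genes the first principal component held 62.7% of the variance and set WT (scores -83.4 to -76.7) furthest from DKO (95 to 107.5). TSC1 KO lay from -57.3 to -37.1, Atg5 KO from -25.7 to -0.3, Nrf2 TKO from -23.8 to 21.3 and p62 TKO from 21.5 to 49.4. The second component (10%) set Atg5 KO (19 to 52) apart from TSC1 KO (-25.1 to -18.6). The 20 most abundant genes took 21% to 26.7% of the counts in WT and 13.3% to 13.7% in DKO. With total counts alone in place of TMM, the median of all genes moved to 0.37 log2 in Atg5 KO versus WT, 0.14 in TSC1 KO versus WT and 1.07 in DKO versus WT, so changes are stated relative to the TMM-scaled median. The corresponding medians were 0.52 for the interaction, 0.67 in DKO versus Atg5 KO, -0.48 in p62 TKO versus DKO, -0.71 in Nrf2 TKO versus DKO, 0.19 in p62 TKO versus Nrf2 TKO, 0.55 in p62 TKO versus WT and 0.39 in Nrf2 TKO versus WT. Genes named below with a direction were beyond the mean of the reference group in 4 of 4 libraries, a count that the interaction does not have.

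**Figure D2:**
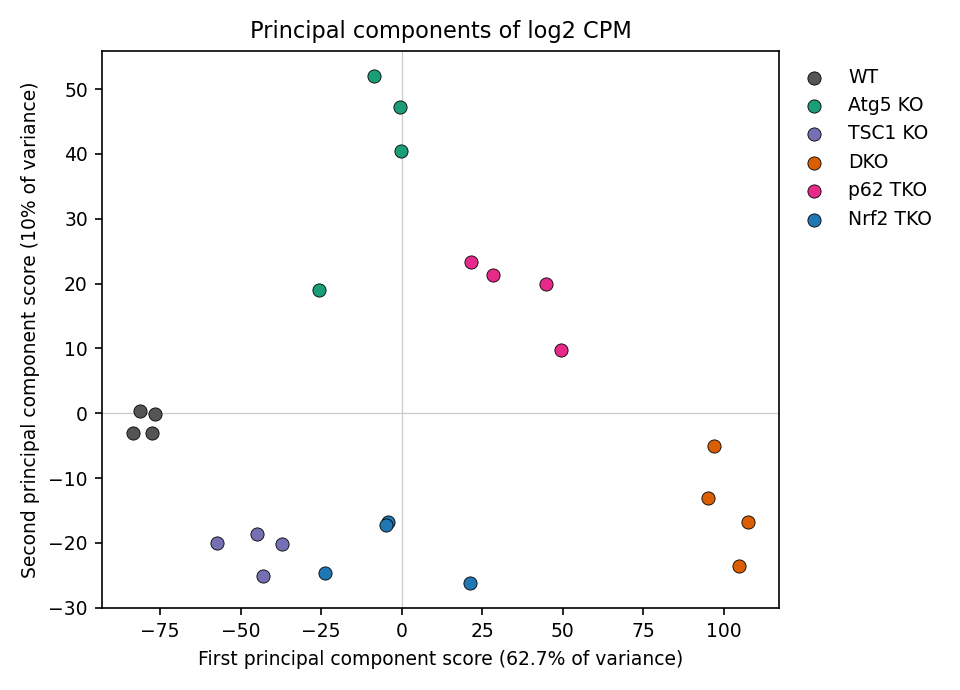
Scores of the 24 libraries on the first (x axis) and second (y axis) principal components of log2 CPM (arbitrary units), computed over the 2000 most variable genes, 1 point per library and 1 colour per genotype. WT and DKO lie at opposite ends of the first component, which holds 62.7% of the variance.

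Livers labelled Atg5 KO, whose Atg5 counts did not show the deletion, were compared with WT for the effect of the Atg5 deletion alone. NRF2 targets, duct markers, fibrosis genes and markers of macrophages and lymphocytes were higher, and hepatocyte and acute-phase genes were lower. Nqo1, a quinone reductase (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206), rose from 5.28 ± 0.38 to 102 ± 38.3 CPM (4.27 ± 0.42, adjusted p = 4.3e-07), and Gstm1, a glutathione transferase whose reads may be shared with its paralogs, rose from 1305 ± 310 to 9099 ± 3010 CPM (2.8 ± 0.34, adjusted p = 3.5e-06). Gpx2, a glutathione peroxidase, was 2705-fold (95% counting interval 485 to 106869.5) higher (fitted log2 10.93, or 12.89 without WT replicate 3). Among the NRF2 targets 27 of 40 rose and none fell (28 adjusted over the list alone), median 1.07, camera adjusted p = 3.8e-17, and the members called included the cystine carrier Slc7a11 (9.44 ± 0.85), the carbonyl reductase Cbr3 (8.16 ± 0.61) and the efflux transporter Abcc4 (6.18 ± 0.45). Cyp2a4 (10.01 ± 1.28, or 11.04 without WT replicate 1), nearly identical to Cyp2a5, was also among the 6 largest increases that met the rule for named genes. Apela, which encodes a small secreted peptide, was at least 712-fold higher, the organic anion carrier Slco4c1 at least 170.5-fold, the urate carrier Slc22a12 at least 108-fold and the glutamate carrier Slc1a1 1409-fold (95% counting interval 389.7 to 11636). The bounds set a floor of 3 counts per group, and all intervals and bounds cover counting error only.

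Markers of bile ducts, scar-forming cells, macrophages and lymphocytes were higher in Atg5 KO. Of the cholangiocyte and ductular genes 23 of 27 rose and none fell (25 adjusted over the list alone), median 2.77, camera adjusted p = 1.8e-24 (adjusted p = 0.046 with an estimated correlation). Spp1, the secreted protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 68.6 ± 12.2 to 708 ± 286 CPM (3.37 ± 0.29, adjusted p = 3.5e-08), and the transcription factor gene Sox4 rose by 3.97 ± 0.36. In the oncofetal and liver tumor list 16 of 22 rose and none fell (17 adjusted over the list alone), median 2.04, camera adjusted p = 1.1e-15 (adjusted p = 0.021 with an estimated correlation). Of the stellate cell and fibrosis genes 26 of 30 rose and none fell (27 adjusted over the list alone), median 1.77, camera adjusted p = 1.8e-17, with Col1a1, a chain of type I collagen, at 3.07 ± 0.35 and the protease inhibitor Timp1 at 3.49 ± 0.44. Macrophage genes moved with them, where 20 of 26 rose and none fell (20 adjusted over the list alone), median 1.84, camera adjusted p = 4.9e-17, and Gpnmb, a glycoprotein of lipid-laden and scar-associated macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), rose by 6.69 ± 0.57 and the receptor gene Trem2 by 3.98 ± 0.41. Lymphocyte genes followed, of which 14 of 18 rose and none fell (14 adjusted over the list alone), median 2.12, camera adjusted p = 1.4e-05, but of the neutrophil genes none of 11 passed (0 adjusted over the list alone), median -0.49, camera adjusted p = 0.37. In the interferon list 18 of 24 rose and 1 fell (19 and 1 adjusted over the list alone), median 1.63, camera adjusted p = 5.4e-15, including the antiviral gene Rsad2 (6.15 ± 0.47) and Ifit1 (4.31 ± 0.43). Of the chemokine and cytokine genes 13 of 24 rose and 1 fell (16 and 1 adjusted over the list alone), median 1.27, camera adjusted p = 4.7e-06, with Ccl5 (4.73 ± 0.47) and Cxcl10 (5.05 ± 0.49) higher and Cxcl1 lower (-3.02 ± 0.79). Cell cycle genes were also higher, 26 of 30 rose and none fell (27 adjusted over the list alone), median 2.24, camera adjusted p = 2.2e-15, as in Top2a (3.63 ± 0.48) and Cdk1 (2.89 ± 0.4).

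Hepatocyte and acute-phase genes were lower in Atg5 KO. Of the acute-phase list 17 of 23 fell and none rose (19 adjusted over the list alone), median -1.64, camera adjusted p = 2.5e-08, and the inhibitor family member Itih4 (-2.16 ± 0.41) and the fibrinogen chain Fgb (-1.49 ± 0.35) were among them. WT itself varied in this list, with library scores against the WT mean of -1.4436 in library 3 and 1.2541 in library 4. Among hepatocyte identity genes 11 of 24 fell and none rose (12 adjusted over the list alone), median -0.63, camera adjusted p = 3.1e-06, and pericentral genes had the same direction, 1 of 20 rose and 11 fell (2 and 11 adjusted over the list alone), median -0.77, camera adjusted p = 0.00016, as in Cyp2e1, an ethanol-metabolising cytochrome (-1.3 ± 0.24), and Cyp2c37 (-2.76 ± 0.49), a member of a family of near copies. The xenobiotic metabolism list was not called, 3 of 25 rose and 4 fell (3 and 4 adjusted over the list alone), median -0.21, or 0.1 with total counts alone, camera adjusted p = 0.19. Alb, which encodes albumin, did not pass (-0.51 ± 0.26, adjusted p = 0.15), but it did so without Atg5 KO replicate 2 (-0.96, adjusted p = 0.0014), the lowest of its group on the first component. The largest decreases were in major urinary protein genes, whose near-identical copies share reads, namely Mup9 (-6.26 ± 1.06), Mup16 (-5.16 ± 0.98), Mup12 (-5.08 ± 1.18), Mup1 (-4.85 ± 0.93) and Mup7 (-4.79 ± 1.19), and in the pseudogene Gtpbp4-ps1 (-5.01 ± 0.81). The test passed 4738 genes, 2944 higher and 1794 lower, against 5719 higher and 349 lower with total counts alone. Leaving out 1 library gave 3582 to 5245 calls.

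Livers labelled TSC1 KO, in which Tsc1 counts did not show the deletion, were compared with WT for the effect of the Tsc1 deletion alone. The lists of duct markers and of lysosome and autophagy genes were higher, while the acute-phase and macrophage lists were lower. Camera called 16 of 30 lists and fry 5, which left out the macrophage list. Gpx3, a secreted glutathione peroxidase, rose from 5.32 ± 0.876 to 336 ± 148 CPM (5.98 ± 0.34, adjusted p = 4.7e-11), and Col5a2, a fibrillar collagen chain, from 3.98 ± 0.77 to 371 ± 208 CPM (6.54 ± 0.51, adjusted p = 4.2e-08). The matrix protease Mmp7 (7.06 ± 1.08), the secreted inhibitor Wfdc12 (6.6 ± 0.98, or 8.92 without WT replicate 2), the cone phosphodiesterase Pde6c (5.54 ± 0.92) and the cholesterol hydroxylase Cyp46a1 (5.46 ± 0.64) were the other largest increases. Of the cholangiocyte and ductular genes 19 of 27 rose and none fell (22 higher and 1 lower adjusted over the list alone), median 2.55, camera adjusted p = 2.3e-31 (adjusted p = 0.033 with an estimated correlation). Spp1 had a change of 3.37 ± 0.29 and Tspan8 of 3.53 ± 0.34. In the lysosome and autophagy list 13 of 33 rose and none fell (14 higher and 1 lower adjusted over the list alone), median 0.31, camera adjusted p = 4.4e-08 (adjusted p = 0.049 with an estimated correlation). Its members included Rragd, a GTPase that signals to mTORC1 (4.54 ± 0.4), the sialidase Neu1 (1.03 ± 0.1), the autophagosome protein gene Gabarapl1 (1.72 ± 0.2) and the protease gene Ctsl (1.0 ± 0.18).

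Acute-phase genes were lower in TSC1 KO, where 19 of 23 fell and none rose (20 adjusted over the list alone), median -1.89, camera adjusted p = 2.8e-11. Saa2 (-8.2 ± 1.9) and Saa1 (-6.48 ± 1.59), near copies of each other, and Lcn2 (-6.49 ± 1.45) had among the largest decreases, and the haemoglobin-binding protein Hp fell less (-3.11 ± 0.48). WT library 4 held the highest acute-phase score of its group, as given above, and without it Saa2 was at -6.53, Saa1 at -5.1 and Lcn2 at -4.63. Moxd1, a monooxygenase, fell from 298 ± 202 to 1.39 ± 1.54 CPM (-7.7 ± 1.01, adjusted p = 5.8e-05, or -8.72 without TSC1 KO replicate 2), Cyp2c69 by 6.2 ± 1.44, and Tmc5 was 65.6-fold (95% counting interval 22.1 to 321) lower, with 3 counts in TSC1 KO replicate 2 and 0 without it. Macrophage and Kupffer cell genes fell as a list, 1 of 26 rose and 11 fell (2 and 13 adjusted over the list alone), median -0.68, camera adjusted p = 0.00036, including Adgre1, the F4/80 antigen (-2.2 ± 0.36), and C1qb of the complement C1q complex (-1.59 ± 0.28), while the tetraspanin Cd63 rose (2.25 ± 0.31). Genes of the ATF4 and unfolded protein list went both ways, 7 of 28 rose and 6 fell (8 and 7 adjusted over the list alone), median 0.17, camera adjusted p = 0.92. In it Nupr1 (3.95 ± 0.43) and the pseudokinase Trib3 (2.55 ± 0.37) rose, whereas the chaperone Hspa5 (-1.36 ± 0.26) and its partner Sdf2l1 (-1.85 ± 0.25) fell. Of the hepatocyte identity genes 1 of 24 rose and 2 fell (1 and 2 adjusted over the list alone), median -0.02, or 0.11 with total counts alone, camera adjusted p = 0.69, and of the NRF2 targets 7 of 40 rose and 1 fell (8 and 1 adjusted over the list alone), median 0.34, camera adjusted p = 0.0081, among them the ferritin chain Ftl1 (1.19 ± 0.25). Oxidative phosphorylation genes were higher, 6 of 30 rose and none fell (8 adjusted over the list alone), median 0.31, camera adjusted p = 0.00042. The test passed 2598 genes, 1393 higher and 1205 lower, against 1851 higher and 628 lower with total counts alone. Without WT replicate 2 the count was 1724.

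Livers labelled DKO were compared with WT for the effect of both deletions, and their Atg5 and Tsc1 counts did not show the deletions. Bile duct and tumor-associated genes rose far above WT while hepatocyte genes fell. Spp1 rose from 68.6 ± 12.2 to 7397 ± 1440 CPM (6.75 ± 0.34, adjusted p = 8.1e-13), and Krt7, a keratin of duct cells, from 1.28 ± 0.233 to 141 ± 9.46 CPM (6.77 ± 0.36, adjusted p = 1.9e-12). Alb (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602) fell from 58760 ± 10600 to 6655 ± 646 CPM (-3.14 ± 0.28, adjusted p = 1.5e-09), and Cyp2e1 from 6958 ± 1130 to 202 ± 59.7 CPM (-5.1 ± 0.28, adjusted p = 1.9e-12). Of the 15851 genes tested 10988 passed, 5873 higher and 5115 lower, against 11158 higher and 1767 lower with total counts alone. In 9855 genes the 4 libraries of one group lay beyond all 4 of the other, where chance gives 2.86%.

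Of the cholangiocyte and ductular genes 26 of 27 rose and 1 fell (26 and 1 adjusted over the list alone), median 5.42, camera adjusted p = 1.5e-20 (adjusted p = 0.045 with an estimated correlation). Sox4 rose by 6.79 ± 0.35, and the tight-junction gene Cldn4 was 1758-fold (95% counting interval 601 to 8525) higher. In the oncofetal and liver tumor list 20 of 22 rose and none fell (20 adjusted over the list alone), median 3.88, camera adjusted p = 6.2e-10 (adjusted p = 0.045 with an estimated correlation), and H19, an imprinted fetal RNA (11.22 ± 1.27), Mmp7 (11.59 ± 1.12) and Anxa2 (3.81 ± 0.28) were among its members. Tbx1, a developmental transcription factor, was at least 636-fold higher, the ribonuclease Rnase1 at least 393-fold and the pseudogene Cbx3-ps8, whose reads its parent gene may share, at least 242-fold. Stellate cell and fibrosis genes were higher, 25 of 30 rose and 2 fell (25 and 2 adjusted over the list alone), median 2.89, camera adjusted p = 1.4e-07. Tgfb2 had a change of 6.78 ± 0.41 and Timp1 of 4.93 ± 0.42. Of the YAP targets 18 of 21 rose and 1 fell (18 and 1 adjusted over the list alone), median 2.02, camera adjusted p = 8.3e-07, including Ankrd1 (8.25 ± 0.67). Of the p53 targets 15 of 20 rose and 3 fell (15 and 3 adjusted over the list alone), median 1.67, camera adjusted p = 0.00018, including the apoptosis gene Pmaip1 (5.28 ± 0.39). Cell cycle genes were higher too, 24 of 30 rose and none fell (25 adjusted over the list alone), median 2.51, camera adjusted p = 5.3e-05. Top2a had a change of 4.26 ± 0.48. Macrophage genes were higher on balance, 19 of 26 rose and 5 fell (19 and 5 adjusted over the list alone), median 1.88, camera adjusted p = 0.00016. Gpnmb had a change of 8.58 ± 0.55 and Cd63 of 6.05 ± 0.33. Chemokine genes were also higher on balance, 14 of 24 rose and 2 fell (14 and 2 adjusted over the list alone), median 1.31, camera adjusted p = 0.025. Cxcl16 had a change of 3.61 ± 0.26.

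Hepatocyte identity genes were lower in DKO, 24 of 24 fell and none rose (24 adjusted over the list alone), median -2.52, camera adjusted p = 1.2e-12, and 0 rose and 22 fell with total counts alone, and the coagulation factor gene F9 fell by 3.48 ± 0.2. Pericentral genes, 1 of 20 rose and 18 fell (1 and 18 adjusted over the list alone), median -4.0, camera adjusted p = 1.3e-10 (adjusted p = 0.045 with an estimated correlation), included Oat (-4.6 ± 0.31) and Cyp2c29 (-5.8 ± 0.39), and periportal genes had the same direction, 1 of 16 rose and 13 fell (1 and 13 adjusted over the list alone), median -2.19, camera adjusted p = 0.0013, with the urea cycle enzyme Cps1 at -3.0 ± 0.35. In the xenobiotic metabolism list 2 of 25 rose and 20 fell (2 and 20 adjusted over the list alone), median -2.44, camera adjusted p = 1.3e-07 (adjusted p = 0.045 with an estimated correlation). For bile acid synthesis and transport 2 of 22 rose and 18 fell (2 and 18 adjusted over the list alone), median -2.69, camera adjusted p = 3.2e-07, including the bile acid importer Slc10a1 (-4.83 ± 0.31). Oxidative phosphorylation genes were lower, 30 of 30 fell and none rose (30 adjusted over the list alone), median -1.26, camera adjusted p = 6.5e-11, but 1 rose and 13 fell with total counts alone, as in Sdha (-1.78 ± 0.16, or -0.79 with total counts alone). Of the fatty acid synthesis genes 19 of 20 fell and none rose (19 adjusted over the list alone), median -1.9, camera adjusted p = 3.5e-08 (adjusted p = 0.045 with an estimated correlation), with the elongase Elovl6 at -3.25 ± 0.22. Of the fatty acid oxidation and PPARA targets 4 of 24 rose and 17 fell (4 and 17 adjusted over the list alone), median -1.62, camera adjusted p = 8.9e-07, with the lipid-binding protein Fabp1 at -5.72 ± 0.48 and the thiolase Acaa2 at -3.01 ± 0.18.

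For cholesterol synthesis 21 of 22 fell and none rose (21 adjusted over the list alone), median -1.62, camera adjusted p = 6.8e-06, as in Dhcr7 (-2.31 ± 0.29, or -1.31 with total counts alone). Gluconeogenesis and amino acid catabolism went with them, 1 of 22 rose and 20 fell (1 and 20 adjusted over the list alone), median -2.51, camera adjusted p = 1.3e-07, and acute-phase genes too, 22 of 23 fell and none rose (22 adjusted over the list alone), median -3.78, camera adjusted p = 3.9e-06. Fgb had a change of -3.84 ± 0.38. The largest decreases were those of the anion carrier Slc22a7, 2881-fold (95% counting interval 797 to 23799) lower, Gtpbp4-ps1, 1193-fold (95% counting interval 329.5 to 9864) lower (fitted log2 -9.75, or -11.59 without DKO replicate 1), Moxd1 (-10.87 ± 1.22), the elongase Elovl3 (-10.3 ± 1.67, or -11.54 without it), the pseudogene Serpina4-ps1 (-10.21 ± 1.23) and the steroid dehydrogenase Hsd3b5 (-10.05 ± 1.33).

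Other lists were not called as a whole. NRF2 targets split, 19 of 40 rose and 11 fell (19 and 11 adjusted over the list alone), median 0.71, camera adjusted p = 0.23, with Abcc4 (6.38 ± 0.45) and the pentose phosphate enzyme G6pdx (4.31 ± 0.33) higher and Mgst1 lower (-2.29 ± 0.17, or -1.3 with total counts alone). In the ATF4 and unfolded protein list 15 of 28 rose and 8 fell (15 and 9 adjusted over the list alone), median 0.95, camera adjusted p = 0.82. Nupr1 had a change of 7.9 ± 0.46 and Hspa5 of -3.18 ± 0.28. Interferon genes also split, 10 of 24 rose and 4 fell (10 and 4 adjusted over the list alone), median 0.5, camera adjusted p = 0.16. Ifit2 had a change of 4.9 ± 0.48. In the glycolysis and HIF list 7 of 18 rose and 9 fell (7 and 9 adjusted over the list alone), median -0.38, or 0.61 with total counts alone, with the camera direction up and the mean 0.31, camera adjusted p = 0.89. Pfkp had a change of 3.9 ± 0.24. For lysosome and autophagy 14 of 33 rose and 8 fell (14 and 8 adjusted over the list alone), median 0.19, camera adjusted p = 0.22, and for cytosolic ribosomal proteins 3 of 40 rose and 4 fell (2 and 4 adjusted over the list alone), median -0.02, or 0.97 with total counts alone, camera adjusted p = 0.82. Of the sex-dependent genes 5 of 19 rose and 8 fell (5 and 8 adjusted over the list alone), median -0.39, or 0.6 with total counts alone, camera adjusted p = 0.31. Slco1a1 had a change of -5.92 ± 0.53. Among cell markers, lymphocyte genes gave 12 of 18 rose and none fell (12 higher and 1 lower adjusted over the list alone), median 2.3, camera adjusted p = 0.064. Cd8a had a change of 5.05 ± 0.75. Liver endothelial genes gave 7 of 18 rose and 4 fell (7 and 4 adjusted over the list alone), median -0.13, or 0.86 with total counts alone, camera adjusted p = 0.89, with Cd34 higher (4.1 ± 0.5) and Clec4g lower (-2.26 ± 0.31, or -1.29 with total counts alone). For neutrophils 2 of 11 rose and none fell (0 higher and 0 lower adjusted over the list alone), median 0.67, camera adjusted p = 0.75, and for red blood cells 1 of 6 fell and none rose (1 adjusted over the list alone), median -0.73, or 0.24 with total counts alone, camera adjusted p = 0.3. The pancreatic acinar and adipocyte lists had 1 and 2 tested members, too few for a list test. Cela1 had a change of -2.16 ± 0.36, or -1.18 with total counts alone, and Car3 fell by 6.19 ± 0.71. Cidec did not pass (0.37 ± 0.44, adjusted p = 0.46) except with total counts alone (1.35, adjusted p = 0.01), and its change was -0.22 without DKO replicate 2.

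**Figure D3:**
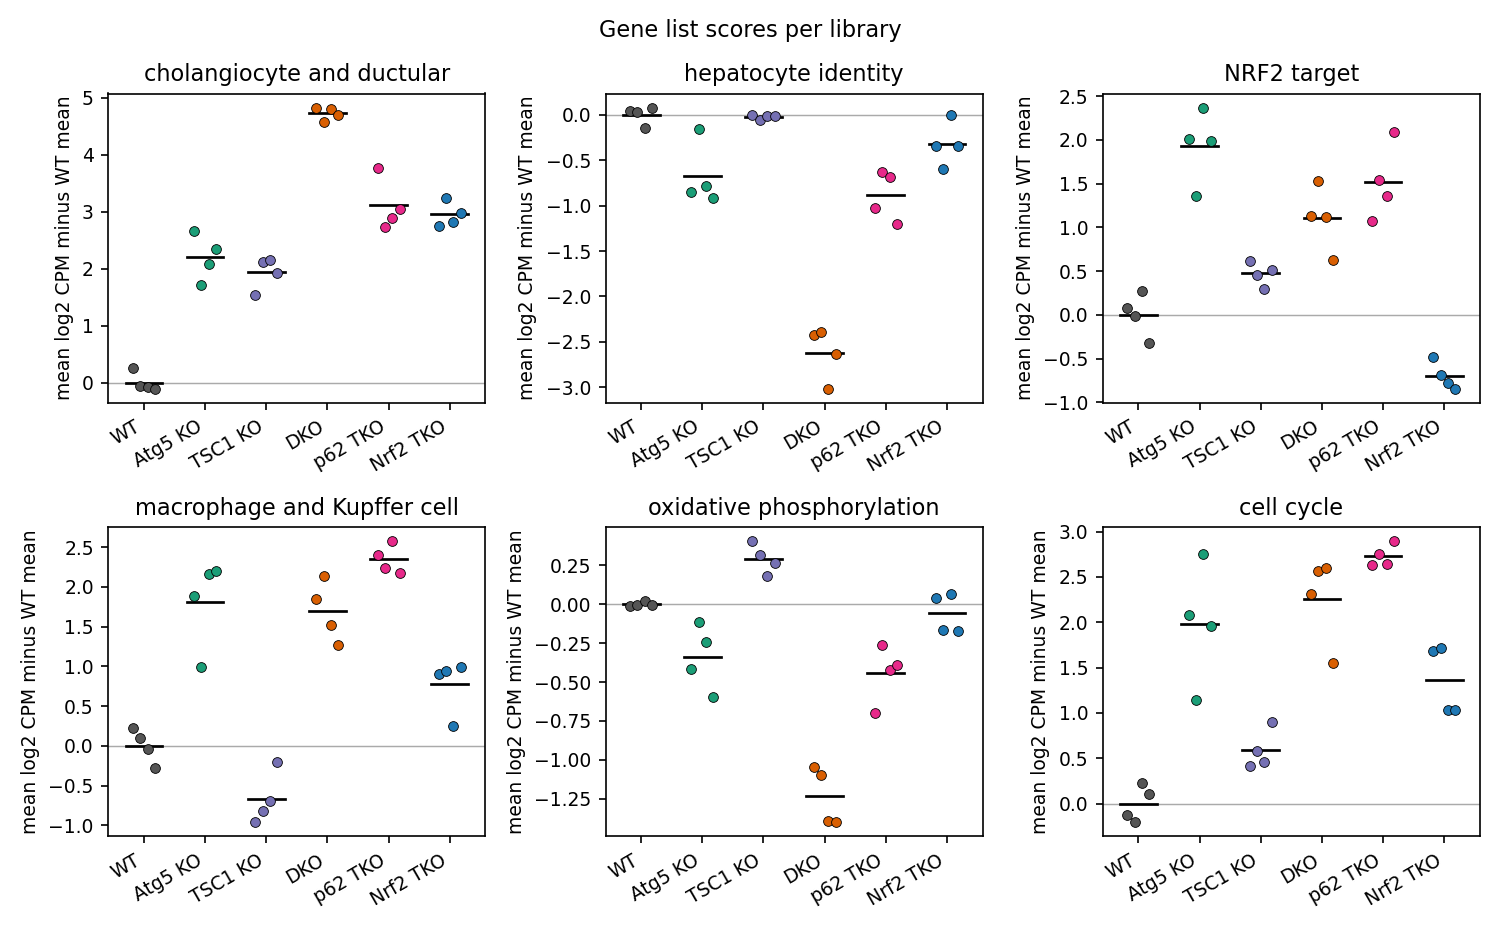
Mean log2 CPM of 6 gene lists in each library minus the WT mean (y axis, log2 units, 0 = WT mean), 1 point per library, with a bar at the mean of each genotype. The cholangiocyte and ductular score reached 4.8241 in DKO library 1, and the NRF2 target score lay at -0.844 to -0.4825 in the 4 Nrf2 TKO libraries.

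Whether the joint loss differed from the sum of the single losses was tested as an interaction, the change from TSC1 KO to DKO minus the change from WT to Atg5 KO, in libraries as labelled. Several lists of hepatocyte genes fell further in the joint loss than the single losses added up to. Cyp2e1 had an interaction of -3.5 ± 0.35, adjusted p = 1.7e-07, and Slc10a1, at 539 ± 66 CPM in WT, 312 ± 55.2 in Atg5 KO and 686 ± 94.3 in TSC1 KO, dropped to 18.9 ± 7.09 in DKO (-4.39 ± 0.39, adjusted p = 5.9e-08). The carboxylesterase gene Ces3a was at 1413 ± 315 and 1654 ± 224 CPM in the single knockouts and 3.71 ± 4.48 in DKO (-8.02 ± 0.92, adjusted p = 1.5e-06, or -9.35 without DKO replicate 1). Of the oxidative phosphorylation genes 30 of 30 were negative and 0 positive (30 and 0 adjusted over the list alone), median -1.15, camera adjusted p = 9.5e-16. Sdhb had a change of -1.7 ± 0.21. With total counts alone 24 were negative. For gluconeogenesis and amino acid catabolism 22 of 22 were negative and 0 positive (22 and 0 adjusted over the list alone), median -2.25, camera adjusted p = 7e-13. Otc had a change of -3.22 ± 0.31. For bile acid genes 18 of 22 were negative and 0 positive (19 and 0 adjusted over the list alone), median -2.2, camera adjusted p = 7.7e-13 (adjusted p = 0.044 with an estimated correlation). For fatty acid synthesis 15 of 20 were negative and 0 positive (16 and 0 adjusted over the list alone), median -1.57, camera adjusted p = 2.3e-10 (adjusted p = 0.028 with an estimated correlation). Elovl6 had a change of -2.48 ± 0.28. For xenobiotic metabolism 19 of 25 were negative and 0 positive (20 and 0 adjusted over the list alone), median -2.28, camera adjusted p = 7.7e-13 (adjusted p = 0.025 with an estimated correlation). Ugt2b36 had a change of -3.9 ± 0.32. For pericentral genes 18 of 20 were negative and 0 positive (19 and 0 adjusted over the list alone), median -2.95, camera adjusted p = 1.6e-14 (adjusted p = 0.028 with an estimated correlation).

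NRF2 targets had a negative interaction, 25 of 40 were negative and 0 positive (26 and 1 adjusted over the list alone), median -1.3, camera adjusted p = 4.7e-07. Gstm4 (-3.34 ± 0.47) and Mgst1 (-1.84 ± 0.23) were among them. Interferon genes had one too, 10 of 24 were negative and 0 positive (10 and 0 adjusted over the list alone), median -0.82, camera adjusted p = 0.0037. Rsad2 had a change of -3.84 ± 0.56. For the cholangiocyte and ductular genes the list interaction did not pass, 5 of 27 were positive and 1 negative (5 and 1 adjusted over the list alone), median 0.38, camera adjusted p = 0.073, although Ezr was positive (1.71 ± 0.35). Igfbp3, a YAP target, was positive (3.16 ± 0.67) and in that list 7 of 21 were positive and 0 negative (7 and 0 adjusted over the list alone), median 0.96, camera adjusted p = 0.0021. Other large positive values were those of Lcn2 (7.04 ± 1.79, or 5.15 without WT replicate 4 and 8.81 without Atg5 KO replicate 4), Chil3 (6.5 ± 1.35), Pde6b (6.18 ± 1.85) and Cyp2c69 (6.32 ± 1.96). Mt2, a metallothionein, had 6.14 ± 1.84, adjusted p = 0.014, but 3.62 and adjusted p = 0.09 without WT replicate 4, and 7.69 without Atg5 KO replicate 4. Large negative values included Elovl3 (-7.59 ± 1.86, or -6.47 without Atg5 KO replicate 2 and -8.87 without DKO replicate 1), Wfdc12 (-7.57 ± 1.59, or -9.95 without WT replicate 2) and the pseudogene Mup-ps19 (-8.11 ± 1.04). The interaction passed for 5517 genes, 2451 positive and 3066 negative, against 5620 positive and 1684 negative with total counts alone.

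DKO was also set against Atg5 KO, both as labelled, for the effect of the Tsc1 deletion beside that of Atg5. Duct genes were higher, and hepatocyte genes and NRF2 targets lower. Krt7 rose from 6.23 ± 2.87 to 141 CPM (4.49 ± 0.3, adjusted p = 1.2e-10) and Cldn4 from 4.63 ± 1.71 to 150 CPM (5.01 ± 0.36, adjusted p = 4.4e-10), and of the cholangiocyte and ductular genes 26 of 27 rose and 1 fell (26 and 1 adjusted over the list alone), median 2.55, camera adjusted p = 3.9e-15. Of the hepatocyte identity genes 23 of 24 fell and none rose (23 adjusted over the list alone), median -1.88, camera adjusted p = 5.8e-12. F9 had a change of -2.93 ± 0.19. Of the NRF2 targets 2 of 40 rose and 25 fell (2 and 25 adjusted over the list alone), median -0.88, camera adjusted p = 0.00054. Mgst1 had a change of -1.95 ± 0.17 and Gstm4 of -2.65 ± 0.34. In the ATF4 and unfolded protein list Nupr1 (6.92 ± 0.42) and the serine synthesis enzyme Phgdh (5.73 ± 0.44) rose, but the list gave 12 of 28 rose and 8 fell (12 and 8 adjusted over the list alone), median 0.5, camera adjusted p = 0.49. The Kupffer cell genes Clec4f (-3.97 ± 0.6) and Cd5l (-3.54 ± 0.57) fell while the macrophage list was not called, 7 of 26 rose and 5 fell (6 and 5 adjusted over the list alone), median 0.07, camera adjusted p = 0.8. Interferon genes were lower, 1 of 24 rose and 13 fell (1 and 13 adjusted over the list alone), median -0.72, camera adjusted p = 0.0052. Rsad2 had a change of -3.16 ± 0.4. Fatty acid synthesis genes were lower, 19 of 20 fell and none rose (19 adjusted over the list alone), median -1.97, camera adjusted p = 9.5e-11 (adjusted p = 0.03 with an estimated correlation). Elovl6 had a change of -3.03 ± 0.21.

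Among the largest increases were those of H19 (9.54 ± 1.1), the neuronal gene Bex2 (7.82 ± 0.82), the muscle gene Myom2, 438-fold (95% counting interval 78.4 to 17344) (fitted log2 8.18, or 9.76 without Atg5 KO replicate 4), the unconventional myosin gene Myo16, at least 95.4-fold, and Prss35, 223-fold (95% counting interval 61.5 to 1844). The largest decreases were those of the ammonium carrier Rhbg, at least 132-fold, Slc22a7, 439.8-fold (95% counting interval 121 to 3640.1), Elovl3 (-9.01 ± 1.62), Ces3a (-8.57 ± 0.8), Hsd3b5 (-8.55 ± 1.29) and Serpina4-ps1 (-8.24 ± 1.17). Without DKO replicate 1, Elovl3 was at -10.27 and Ces3a at -9.88, and without Atg5 KO replicate 2 Elovl3 was at -7.9. Against Atg5 KO, 8949 genes passed, 4627 higher and 4322 lower, against 9156 higher and 1955 lower with total counts alone.

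The p62 TKO livers were compared with DKO for the effect of further p62 loss. Sqstm1 and Tsc1 were lower, as given above, while Atg5 was below TSC1 KO but not WT. Hepatocyte genes were higher and duct genes lower than in DKO. Cyp2e1 rose from 202 to 2081 ± 186 CPM (3.36 ± 0.26, adjusted p = 4.6e-09), Alb from 6655 to 18270 ± 3450 CPM (1.46 ± 0.27, adjusted p = 0.00013) and the complement gene C8a from 6.94 ± 3.62 to 437 ± 199 CPM (5.98 ± 0.59, adjusted p = 1.4e-07). Cldn4 fell from 150 to 14.3 ± 8.94 CPM (-3.39 ± 0.33, adjusted p = 8.6e-08) and Krt7 from 141 to 25.5 ± 13.7 CPM (-2.47 ± 0.26, adjusted p = 2.9e-07). Of the hepatocyte identity genes 23 of 24 rose and none fell (23 adjusted over the list alone), median 1.52, camera adjusted p = 2e-15. F9 had a change of 2.65 ± 0.19. Of the cholangiocyte and ductular genes 24 of 27 fell and none rose (24 adjusted over the list alone), median -1.53, camera adjusted p = 7.2e-13. Pericentral genes gave 18 of 20 rose and none fell (18 adjusted over the list alone), median 2.5, camera adjusted p = 9e-15 (adjusted p = 0.034 with an estimated correlation). In the xenobiotic list 20 of 25 rose and none fell (21 adjusted over the list alone), median 1.8, camera adjusted p = 3.7e-12 (adjusted p = 0.028 with an estimated correlation). Ugt2b36 had a change of 2.96 ± 0.23. Oxidative phosphorylation genes were higher, 30 of 30 rose and none fell (30 adjusted over the list alone), median 0.79, camera adjusted p = 1.2e-11, and 15 rose and 0 fell with total counts alone. Cycs had a change of 1.5 ± 0.15. Fatty acid oxidation genes gave 21 of 24 rose and none fell (21 adjusted over the list alone), median 1.37, camera adjusted p = 7.7e-13. Fabp1 had a change of 4.61 ± 0.46. Bile acid genes gave 18 of 22 rose and none fell (19 higher and 1 lower adjusted over the list alone), median 1.87, camera adjusted p = 3.1e-11. Slc10a1 had a change of 3.05 ± 0.29.

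Acute-phase genes were higher in p62 TKO than in DKO, 21 of 23 rose and none fell (21 adjusted over the list alone), median 2.07, camera adjusted p = 3.1e-07. Saa4 had a change of 4.24 ± 0.61. Of the YAP targets 1 of 21 rose and 11 fell (1 and 12 adjusted over the list alone), median -0.73, camera adjusted p = 9.2e-05, with Tgfb2 (-2.11 ± 0.29) and Fjx1 (-2.87 ± 0.4) lower. In the oncofetal and liver tumor list 2 of 22 rose and 8 fell (2 and 8 adjusted over the list alone), median -0.4, camera adjusted p = 0.031, and the imprinted gene Peg3 fell by 3.21 ± 0.35. Of the NRF2 targets 16 of 40 rose and 2 fell (16 and 2 adjusted over the list alone), median 0.61, camera adjusted p = 0.033, with Mgst1 at 1.3 ± 0.16, or 0.83 with total counts alone. The macrophage list was not called, 5 of 26 rose and none fell (5 adjusted over the list alone), median 0.2, or -0.25 with total counts alone, camera adjusted p = 0.27, although the Kupffer cell genes Timd4 (4.83 ± 0.58) and Clec4f (3.65 ± 0.59) were higher. Other large increases were those of Wfdc12 (6.66 ± 0.84), Ces3a (6.11 ± 0.72, or 7.41 without DKO replicate 1), the sulfotransferase Sult2a8 (5.37 ± 0.62, or 6.4 without the same library), and, with copies that share reads, Mup20 (5.9 ± 0.74) and Mup-ps19 (6.92 ± 0.87). Large decreases were those of the ubiquitin hydrolase Uchl1 (-4.34 ± 0.52), Fxyd2 (-4.3 ± 0.52), Prss35 (-4.06 ± 0.58), Fgfbp1 (-3.78 ± 0.37), Serpinb9b (-3.78 ± 0.53) and Map3k9 (-3.75 ± 0.47). Against DKO, 6946 genes passed in p62 TKO, 3533 higher and 3413 lower, against 1624 higher and 7544 lower with total counts alone.

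The Nrf2 TKO livers were compared with DKO for the effect of further Nrf2 loss. Nfe2l2 was lower, Atg5 was below TSC1 KO but not WT, and Tsc1 did not show its deletion. NRF2 targets fell below DKO, and hepatocyte genes were higher. Nqo1 fell from 80.5 ± 19.4 to 3.83 ± 2.02 CPM (-4.37 ± 0.42, adjusted p = 3e-08), Gstm1 from 4657 ± 1080 to 442 ± 166 CPM (-3.4 ± 0.35, adjusted p = 4.2e-08) and Slc7a11 from 136 ± 71.1 to 1.33 ± 1.18 CPM (-6.69 ± 0.68, adjusted p = 9.5e-08). Alb rose from 6655 to 45980 ± 6200 CPM (2.79 ± 0.28, adjusted p = 2.6e-08). Of the NRF2 targets 2 of 40 rose and 28 fell (2 and 29 adjusted over the list alone), median -1.33, camera adjusted p = 2.5e-07. Abcc4 had a change of -4.78 ± 0.4 and G6pdx of -3.13 ± 0.3. Of the hepatocyte identity genes 24 of 24 rose and none fell (24 adjusted over the list alone), median 2.33, camera adjusted p = 2.3e-16. Cyp2e1 had a change of 4.48 ± 0.27 and F9 of 2.79 ± 0.19. Of the cholangiocyte and ductular genes 23 of 27 fell and none rose (24 adjusted over the list alone), median -1.64, camera adjusted p = 1.4e-09. Krt7 had a change of -3.04 ± 0.27 and Cldn4 of -4.42 ± 0.35. In the oncofetal and liver tumor list 18 of 22 fell and none rose (20 adjusted over the list alone), median -1.88, camera adjusted p = 8.5e-07. Akr1b8 had a change of -2.81 ± 0.29. Macrophage genes were lower, 5 of 26 rose and 19 fell (5 and 20 adjusted over the list alone), median -1.24, camera adjusted p = 0.00056. Gpnmb had a change of -4.65 ± 0.37 and Trem2 of -3.07 ± 0.35.

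Oxidative phosphorylation genes were higher in Nrf2 TKO than in DKO, 30 of 30 rose and none fell (30 adjusted over the list alone), median 1.17, camera adjusted p = 2.9e-16, and 24 rose and 0 fell with total counts alone, with Cycs at 1.78 ± 0.15, or 1.09 with total counts alone. For gluconeogenesis and amino acid catabolism 21 of 22 rose and none fell (21 adjusted over the list alone), median 2.59, camera adjusted p = 5.2e-13, with Otc at 3.34 ± 0.23, for fatty acid oxidation 21 of 24 rose and none fell (21 adjusted over the list alone), median 1.4, camera adjusted p = 4.9e-11. Fabp1 had a change of 6.04 ± 0.49. For fatty acid synthesis 16 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), median 1.26, camera adjusted p = 5.9e-07. Mlxipl had a change of 2.97 ± 0.2. Cell cycle genes were lower, 16 of 30 fell and none rose (19 adjusted over the list alone), median -1.08, camera adjusted p = 0.014. Aurkb had a change of -1.74 ± 0.43. YAP targets fell too, 16 of 21 fell and none rose (17 adjusted over the list alone), median -1.23, camera adjusted p = 1.2e-05. Tgfb2 had a change of -3.4 ± 0.31, and Pmaip1 fell by 3.76 ± 0.33 while the p53 list was not called, 2 of 20 rose and 9 fell (2 and 9 adjusted over the list alone), median -0.29, camera adjusted p = 0.32. Prm1, a sperm chromatin protein, was at least 171-fold higher, and Mug4-ps (10.14 ± 1.98) held 0.792, 0.595, 299 and 175 CPM in the 4 Nrf2 TKO libraries. Other large increases were those of Ces3a (8.12 ± 0.79), Elovl3 (8.02 ± 1.58, or 5.79 without Nrf2 TKO replicate 3), Sult2a8 (7.59 ± 0.68) and Mup3 (7.41 ± 0.85). Without DKO replicate 1 they were at 9.43, 9.28, 8.64 and 9.09. Large decreases were those of Gpx2 (-8.31 ± 0.76) and Apela (-6.64 ± 0.94), at -10.14 and -7.94 without Nrf2 TKO replicate 1, S100b (-6.22 ± 0.44), Slc5a9, 115-fold (95% counting interval 31.6 to 951), and Fxyd2, 81.9-fold (95% counting interval 27.8 to 399). Xist, the X-inactivation RNA, was chosen after its values were seen. Nrf2 TKO library 2 held it at 1050 CPM, against at most 4.65 in the 23 others, and the sex-dependent list, 10 of 19 rose and 1 fell (10 and 1 adjusted over the list alone), median 2.66, camera adjusted p = 0.25, passed without that library (adjusted p = 0.021). In total 8861 genes passed, 4228 higher and 4633 lower, against 1826 higher and 9483 lower with total counts alone.

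Both triple knockouts were then set against the changes of DKO versus WT. Of the 10988 genes called in DKO versus WT, 6063 (55.2%) were called in the opposite direction in p62 TKO versus DKO and 122 in the same direction. For Nrf2 TKO versus DKO the counts were 7587 (69%) and 81. Independent lists of these sizes would share 1265 genes higher in DKO and 1140 lower in DKO for p62 TKO, where 3030 and 3033 were seen. For Nrf2 TKO they would share 1717 and 1364, where 3965 and 3622 were seen. The comparisons share the DKO libraries, and 20 simulations kept the DKO change and left the triple knockouts unchanged from DKO. They called 10351 to 10441 genes in DKO versus WT and at most 1 in the opposite direction in either triple knockout, with a mean correlation of -0.079 across genes between the DKO change and the p62 TKO change. The observed correlation was -0.79, or -0.75 with the DKO libraries split so that none was on both sides. The covariance was -1.363 against -0.043 in the second simulations. With the split libraries, the slope of the p62 TKO change on the DKO change was -0.39 (from -0.42 to -0.36 over 6 splits), and that of the Nrf2 TKO change was -0.57 (from -0.61 to -0.52). For Nrf2 TKO the correlation was -0.87 (split -0.83) and the covariance -1.945. Against DKO, 2948 genes were higher in both triple knockouts (independent lists, 942), 2853 lower in both (998) and 49 opposite, with a correlation of 0.83 (split 0.78, simulated 0.478) and a covariance of 0.967 (simulated 0.043). DKO is the reference of both comparisons, so what sets DKO itself apart adds to this agreement. Genes are not independent replicates in these correlations.

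**Figure D4:**
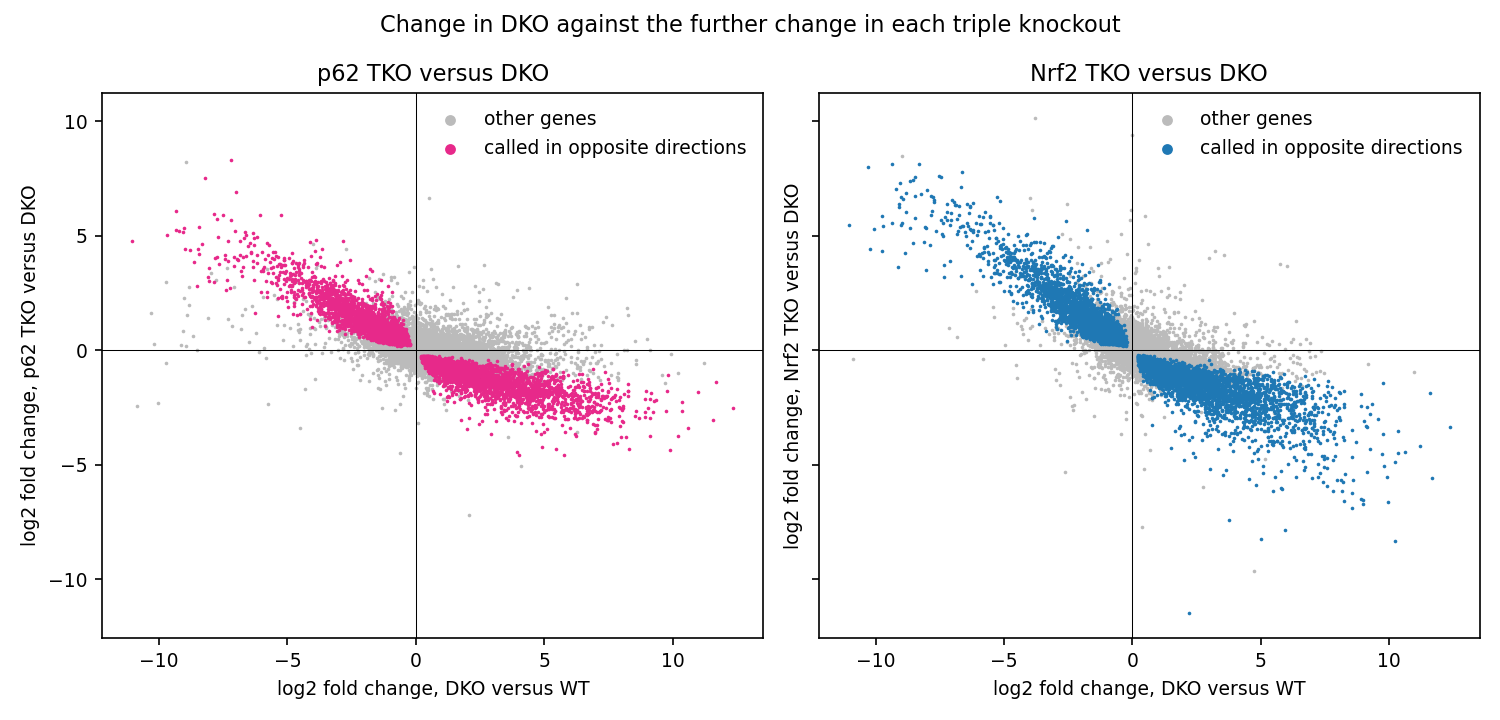
Log2 fold change of each of the 15851 genes tested in DKO versus WT (x axis) against that in p62 TKO versus DKO (left) and Nrf2 TKO versus DKO (right, y axis), with genes called in opposite directions in colour and the others in grey. Opposite calls number 6063 on the left and 7587 on the right, and both axes share the DKO libraries.

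The triple knockouts were compared with each other as the test of whether p62 and Nrf2 loss differed. NRF2 targets and macrophage genes separated them. Gstm1 was at 5664 CPM in p62 TKO and 442 in Nrf2 TKO (3.68 ± 0.36, adjusted p = 6.2e-07), and Gpnmb at 39.1 ± 12.1 and 2.26 ± 1.14 CPM (4.07 ± 0.37, adjusted p = 3.3e-07). Of the NRF2 targets 34 of 40 rose and none fell (35 adjusted over the list alone), median 1.59, camera adjusted p = 1.2e-43 (adjusted p = 0.045 with an estimated correlation), with Slc7a11 (7.2 ± 0.69), Gsta1 (6.62 ± 0.72), Cbr3 (5.28 ± 0.51) and Abcc4 (4.04 ± 0.39) among them, and Gpx2 was higher as well (7.32 ± 0.78, or 9.19 without Nrf2 TKO replicate 1). Of the macrophage genes 22 of 26 rose and none fell (23 adjusted over the list alone), median 1.47, camera adjusted p = 1.7e-20. Trem2 had a change of 2.57 ± 0.35. In the oncofetal and liver tumor list 12 of 22 rose and none fell (15 adjusted over the list alone), median 1.5, camera adjusted p = 7.7e-10 (adjusted p = 0.045 with an estimated correlation). Cd44 had a change of 1.54 ± 0.22 and Anxa2 of 1.72 ± 0.25. Cell cycle genes were higher in p62 TKO, 21 of 30 rose and none fell (22 adjusted over the list alone), median 1.44, camera adjusted p = 3.3e-13, with Ccnb1 at 2.35 ± 0.43 and Cdk1 at 1.77 ± 0.33, and interferon genes too, 10 of 24 rose and none fell (12 adjusted over the list alone), median 0.65, camera adjusted p = 6.4e-05. Rsad2 had a change of 2.47 ± 0.4. Among the cholangiocyte and ductular genes 2 of 27 rose and 1 fell (2 and 1 adjusted over the list alone), median 0.2, camera adjusted p = 0.37. Some metabolic lists were lower in p62 TKO, others were not called. For gluconeogenesis and amino acid catabolism 11 of 22 fell and none rose (17 adjusted over the list alone), median -0.97, camera adjusted p = 1.8e-09, with Oat at -1.4 ± 0.27 and Got1 at -1.81 ± 0.33, and for oxidative phosphorylation 14 of 30 fell and none rose (17 adjusted over the list alone), median -0.37, camera adjusted p = 9.7e-09, and 0 rose and 2 fell with total counts alone. Cox7b had a change of -0.88 ± 0.13. Of the hepatocyte identity genes 7 of 24 fell and none rose (10 adjusted over the list alone), median -0.46, camera adjusted p = 1.6e-05. Alb had a change of -1.33 ± 0.27.

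Beside Gpx2, Slc7a11 and Gsta1, large increases in p62 TKO over Nrf2 TKO were those of Serpinb9e, 249.6-fold (95% counting interval 68.8 to 2066) (fitted log2 7.63, or 10.07 without Nrf2 TKO replicate 1), the lipase Lipn, 224-fold (95% counting interval 39.8 to 8879) (fitted log2 7.27, or 8.97 without Nrf2 TKO replicate 4), and Slc1a1 (6.6 ± 0.64). Large decreases were those of Prm1, 360.3-fold (95% counting interval 64.2 to 14278) (fitted log2 -7.88, or -9.41 without p62 TKO replicate 3), the hepcidin paralog Hamp2 (-5.59 ± 0.88), Mup3 (-3.55 ± 0.71), Slco1a1 (-3.44 ± 0.49) and Hsd3b5, 233-fold (95% counting interval 64.2 to 1934) with adjusted p = 0.0079. Without Nrf2 TKO replicate 3 the fitted log2 change of Hsd3b5 went from -7.61 to -4.21 (adjusted p = 0.11). Mup18 (-4.05 ± 1.05, adjusted p = 0.012) lost its call without that library, with a smaller change (-2.73, adjusted p = 0.066) and, at the same change, with only these groups fitted (-4.05 ± 1.14, adjusted p = 0.058). Between them 2776 genes passed, 1649 higher and 1127 lower in p62 TKO, against 2987 higher and 549 lower with total counts alone. With only the groups compared in the fit the count was 1677.

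Both triple knockouts were finally compared with WT for what still differed in them. In p62 TKO, duct and macrophage genes lay above WT and hepatocyte genes below it. Spp1 stood at 2858 ± 536 CPM (5.38 ± 0.32, adjusted p = 6e-11), and the changes were 8.0 ± 0.55 for Gpnmb, 5.64 ± 0.44 for Abcc4, -1.74 ± 0.24 for Cyp2e1 and -1.69 ± 0.27 for Alb. Among the cholangiocyte and ductular genes 26 of 27 rose and 1 fell (26 and 1 adjusted over the list alone), median 4.07, camera adjusted p = 2.7e-23, and of the oncofetal and liver tumor list 20 of 22 rose and none fell (20 adjusted over the list alone), median 2.91, camera adjusted p = 2.9e-16 (adjusted p = 0.014 with an estimated correlation). Of the macrophage genes 20 of 26 rose and none fell (20 adjusted over the list alone), median 2.08, camera adjusted p = 6e-13, of the NRF2 targets 25 of 40 rose and 5 fell (26 and 6 adjusted over the list alone), median 0.94, camera adjusted p = 7.5e-05 and of the hepatocyte identity genes 18 of 24 fell and none rose (19 adjusted over the list alone), median -0.85, camera adjusted p = 6.2e-06. Large increases were those of H19 (10.67 ± 1.26), Slc7a11 (9.5 ± 0.85), Rnase1, at least 152-fold, Serpinb9e, at least 132-fold, Tbx1, at least 111-fold, and Apela, at least 106-fold. Large decreases were those of Moxd1, 15089-fold (95% counting interval 2708 to 596055) (fitted log2 -13.3, or -14.83 without p62 TKO replicate 4), Hsd3b5, 6730.3-fold (95% counting interval 1863 to 55583), Serpina4-ps1 (-9.95 ± 1.23) and the urinary protein copies Mup7 (-10.32 ± 1.53), Mup9 (-8.9 ± 1.27) and Mup11 (-8.75 ± 1.53, or -10.04 without p62 TKO replicate 3). In total 8068 genes passed, 4431 higher and 3637 lower, against 8572 higher and 988 lower with total counts alone.

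In Nrf2 TKO, duct genes lay above WT and NRF2 targets lay below it. Spp1 stood at 2036 ± 597 CPM (4.89 ± 0.31, adjusted p = 3.5e-10), the change of Col5a2 was 7.58 ± 0.53, and of the cholangiocyte and ductular genes 25 of 27 rose and 1 fell (26 and 1 adjusted over the list alone), median 3.74, camera adjusted p = 1.3e-33 (adjusted p = 0.023 with an estimated correlation). Of the NRF2 targets 2 of 40 rose and 20 fell (3 and 21 adjusted over the list alone), median -0.6, camera adjusted p = 8.1e-07, with the carboxylesterase Ces1g (-3.65 ± 0.41), Aox1 (-2.66 ± 0.24) and the malic enzyme Me1 (-2.66 ± 0.32) lower. Of the stellate cell and fibrosis genes 23 of 30 rose and none fell (25 adjusted over the list alone), median 1.82, camera adjusted p = 1.3e-11, and of the cell cycle genes 22 of 30 rose and none fell (22 adjusted over the list alone), median 1.53, camera adjusted p = 6.4e-06. Of the hepatocyte identity genes 8 of 24 fell and none rose (8 adjusted over the list alone), median -0.3, or 0.01 with total counts alone, camera adjusted p = 0.02, and Alb did not pass (-0.35 ± 0.26, adjusted p = 0.29). In the cholesterol synthesis list 19 of 22 fell and none rose (19 adjusted over the list alone), median -0.93, camera adjusted p = 1.6e-09. Large increases were those of Mmp7 (9.73 ± 1.09), Cbx3-ps8, at least 128-fold, Prm1, at least 81.6-fold, and Tbx1, at least 63.3-fold. Cyp2b9, 1116-fold (95% counting interval 382 to 5414), held 275 CPM in library 2 and 8.32, 21.3 and 20.6 CPM in libraries 1, 3 and 4. Without library 2 its fitted log2 change went from 9.74 to 7.45, and without WT replicate 1 to 10.74. Large decreases were those of Moxd1 (-11.24 ± 1.32), the protease Capn8 (-6.24 ± 0.54), the tautomerase Dct (-6.17 ± 0.69, or -7.54 without Nrf2 TKO replicate 3), Serpina12 (-5.72 ± 0.73), Serpina4-ps1 (-5.79 ± 0.95, or -6.91 without the same library) and Slc22a7 (-5.59 ± 0.5). In total 6262 genes passed, 3547 higher and 2715 lower, against 6166 higher and 1004 lower with total counts alone. With only the groups compared in the fit the count was 3691.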

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

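The tests of male RNA mixed into Nrf2 TKO library 2 and of another genotype in it were chosen only after its values were seen. Within groups of 4 libraries, a library was singled out when its gap to the nearest other exceeded Dixon's 95% critical value. Chance flags about 1 in 20 groups, and 16 of 176 groups were singled out.

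In Nrf2 TKO library 2, Xist stood at 1050 CPM against 0.198 to 4.65 in the 3 others, and the Y-linked Ddx3y at 0.372 CPM against 80.1 to 91.2. A female animal may explain this, since 15 of 15 autosomal sex-biased genes (100%) lay beyond the 3 other libraries on the side a female would lie. The tables argue against male RNA mixed in, because Y-linked transcripts were 0.28% of the mean of the others. They also argue against a library of another genotype with Nfe2l2, whose count was 17.7 CPM, under 46.4 CPM, 0.5 of the lowest DKO library. Sex is not in the labels and its effect within the group was not tested.

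WT library 4 held 26.7% of its counts in the 20 most abundant genes, against 21% to 21.6% in the other WT libraries. Atg5 KO library 2 held 22.2% there, against 16.9% to 17.2%. Tsc1 stood at 45.6 CPM in the same Atg5 KO library, against 27.5 to 28.9 CPM. In DKO, Ces3a stood at 10.4 CPM in library 1, against 0.943 to 2.16, and Nfe2l2 at 162 CPM in library 4, against 92.8 to 99.9. In Nrf2 TKO, Slc7a11 stood at 3.07 CPM in library 1, against 0.484 to 0.892, and Sqstm1 at 975 CPM in library 4, against 535 to 575. Spp1 stood at 50.4 CPM in WT library 3, against 73.8 to 76.2. Xist stood at 0.379 CPM in TSC1 KO library 2, against 0.0966 to 0.109.

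Scores of gene lists, in log2 units against the WT mean, singled out further libraries. The cholangiocyte and ductular score was 0.25 in WT library 1, against -0.11 to -0.06 in the other WT libraries. The hepatocyte identity score was -0.05 in TSC1 KO library 2, against -0.01 in each of the others. The macrophage and Kupffer cell score was 0.25 in Nrf2 TKO library 3, against 0.9 to 1.0. The acute-phase score was -1.9 in TSC1 KO library 4, against -2.23 to -2.21. The score of sex-dependent and sex-chromosome genes was -0.11 in TSC1 KO library 2, against 0.39 to 0.47.

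A pair of differences between effects passed a test of the difference itself in edgeR. In libraries as labelled, the change from TSC1 KO to DKO differed from the change from WT to Atg5 KO in 5517 genes, and the change from DKO to p62 TKO differed from that to Nrf2 TKO in 2776.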

How the results depend on the processing

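Chosen only after the results were seen were the tests without the 20 most abundant genes and the list tests without Nrf2 TKO library 2 or without Atg5 KO library 2. Under DESeq2, DESeq2 size factors, total counts alone and no filter on low counts, the number of called genes lay within 1.5 times that reported in each of the 10 comparisons and for the opposed changes. Total counts alone changed directions, and the number of called genes with the opposite call was 1303 in DKO versus WT, 227 in DKO versus Atg5 KO, 5 in p62 TKO versus DKO, 287 in Nrf2 TKO versus DKO, 75 in p62 TKO versus WT and 0 in the others. With only the groups compared in the fit, p62 TKO versus Nrf2 TKO called 1677 genes and Nrf2 TKO versus WT 3691, and the cause was not tested. Called genes were 10912 in DKO versus WT without the 20 most abundant genes of each group. For gene lists, 182 of 300 tests passed with the preset correlation and 22 with an estimated one, each in the same direction. Fry passed 187, of which 162 were among the 182, but it does not compare a list with other genes. Without Nrf2 TKO library 2 the number was 187, of which 179 were among the 182, and without Atg5 KO library 2 it was 184, of which 180 were.

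Leaving out 1 library gave 3582 to 5245 called genes in Atg5 KO versus WT, 1724 to 2272 in TSC1 KO versus WT, 10523 to 10836 in DKO versus WT, 4888 to 5500 for the interaction, 8322 to 8747 in DKO versus Atg5 KO, 5946 to 6995 in p62 TKO versus DKO, 8108 to 8974 in Nrf2 TKO versus DKO, 2040 to 2888 between the triple knockouts, 7144 to 8050 in p62 TKO versus WT and 4845 to 6944 in Nrf2 TKO versus WT. Opposed changes numbered 5241 to 6113 for p62 loss and 6915 to 7907 for Nrf2 loss. The lowest in TSC1 KO versus WT was without WT replicate 2, and in Nrf2 TKO versus WT without Nrf2 TKO replicate 2. The causes were not tested.

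For named genes, 4351 of 4361 values under these alternatives had the direction and the side of the threshold reported. Called genes lost the call in 5 (3 without 1 library, 1 with only the groups compared, 1 with total counts alone), uncalled genes passed in 3 (2 without 1 library, 1 with total counts alone), and 2 changed sign, of genes not called. Sqstm1 in p62 TKO versus WT, which did not pass, changed to 0.18 with total counts alone. Cidec in DKO versus WT, which did not pass either, lay between -0.22 and 0.62 without 1 library (DKO replicate 2 and 3), but passed at 1.35 with total counts alone.

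The labels give the groups the same replicate numbers, but nothing in them says that a number marks a shared animal, litter or day. Deviations from the group means did not pair the libraries either, since in each comparison of 2 genotypes at most 1 of 4 pairs with the same number correlated above 0.1, and in none did every library correlate best with its own number. With the number as a replicate block, the comparisons in the order above called 4607, 2469, 10912, 5388, 8859, 6889, 8775, 2625, 7938 and 6150 genes, and 183 list tests passed. The block changed no call of a named gene.

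Among 35 splits of the 8 libraries compared (100 drawn for the interaction), only the real split called more than 1 gene. Other splits mix genotypes, which widens the spread, so chance assignment is not excluded. Real and highest other counts in fits of only the groups compared were 3593 and 1 for Atg5 KO versus WT, 2793 and 1 for TSC1 KO versus WT, 10236 and 0 for DKO versus WT, 5730 and 0 for the interaction, 8501 and 0 for DKO versus Atg5 KO, 7004 and 1 for p62 TKO versus DKO, 7467 and 0 for Nrf2 TKO versus DKO, 1677 and 0 between the triple knockouts, 7158 and 0 for p62 TKO versus WT and 3691 and 0 for Nrf2 TKO versus WT. With few genes changed, simulations recovered 22% of 1.5-fold changes.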

Other observations

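The tests without the 20 most abundant genes were chosen only after the results were seen, and the Kupffer cell, macrophage and stress genes named first were chosen after their values were seen. Differences between these genes were not tested. Clec4f, a Kupffer cell lectin, stood at 69 ± 17.6 CPM in WT, 91.8 ± 42.7 in Atg5 KO and 5.92 ± 5.31 in DKO, where it was lower than in WT (-3.56 ± 0.59, adjusted p = 2.3e-05). It was higher than in DKO at 73.8 ± 23.9 CPM in p62 TKO (3.65 ± 0.59, adjusted p = 5.7e-05) and 36.5 ± 6.29 in Nrf2 TKO (2.64 ± 0.58, adjusted p = 0.00065). Cd5l was lower than in WT in both TSC1 KO (-2.46 ± 0.55) and DKO (-3.08 ± 0.56), and higher in p62 TKO than in DKO (3.71 ± 0.57). Trem2 and Gpnmb rose in DKO versus WT by 4.5 ± 0.4 and 8.58 ± 0.55, and Gpnmb stood at 0.32 ± 0.109 CPM in TSC1 KO, 58.5 ± 35.1 in DKO and 2.26 ± 1.14 in Nrf2 TKO.

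Hspa5, a chaperone of the endoplasmic reticulum, and the stress gene Nupr1 were both in the ATF4 and unfolded protein list, which was not called in DKO versus WT (camera adjusted p = 0.82). Hspa5 stood at 2560 ± 718 CPM in WT, 1072 ± 336 in Atg5 KO (-1.26 ± 0.26, adjusted p = 0.001), 996 ± 146 in TSC1 KO and 282 ± 38.8 in DKO, and its interaction did not pass (-0.57 ± 0.37, adjusted p = 0.25). Nupr1 stood at 1.37 ± 0.285, 2.71 ± 0.764, 21.3 ± 7.27 and 328 ± 107 CPM in these groups, and its interaction passed (2.97 ± 0.62, adjusted p = 0.00083). In p62 TKO versus DKO, Hspa5 rose by 1.27 ± 0.26, or by 0.81 with total counts alone, and Nupr1 fell by 2.48 ± 0.33. In Nrf2 TKO versus DKO, Hspa5 rose by 1.74 ± 0.27, or by 1.04 with total counts alone, and Nupr1 fell by 2.38 ± 0.33.

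A lower hepatocyte share of the RNA would raise the markers of every other cell type alike. In DKO versus WT the list medians of 5 other cell types ran from -0.13 (liver endothelial, quartiles -0.59 and 0.75) to 5.42 (cholangiocyte and ductular, quartiles 3.35 and 6.66). They thus lay 5.55 apart, which argues against that share as the whole cause, while a change in the cells that rose stays open. GC content and gene length accounted for 2.41% of the variance of log2 fold changes, which argues against them. Without the 20 most abundant genes of each group 10912 genes were called, but TMM trims such genes, so this count decides nothing about a few genes taking most of the counts. With total counts alone, leaving them out moved the median log2 fold change of all genes from 1.07 to 0.84. That shift, 0.23, is under the lower quartile of the size of called changes (0.75, median 1.36), which argues against a shift by these genes as the whole cause. Cell composition was not measured, so a change of state in hepatocytes and a change of cell numbers both remain possible.

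Flanking DNA of a targeted allele could add calls near it. Within 10 Mb of Atg5, 35.1% of tested genes were called in Atg5 KO versus WT, against 29.2% on the rest of the chromosome. Near Tsc1 it was 19.4% against 15.9% in TSC1 KO versus WT, and near Sqstm1 47.2% against 43.6% in p62 TKO versus DKO. One-sided Fisher exact tests gave adjusted p = 0.28 for each of these, so a local effect and none cannot be told apart there, since the excess is smaller than these numbers of genes can show. Near Nfe2l2 the share was 54.7% in Nrf2 TKO versus DKO, against 55.8% on the rest of the chromosome, which argues against an excess of calls there.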
